A study of Mus musculus with 6 samples.

How the data were processed

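Gene expression was measured with 6 Agilent 1-colour mouse arrays hybridised with Cy3-labelled RNA from mouse embryonic fibroblasts at day 8 of reprogramming. Per the labels, all cultures were infected with the factors abbreviated SKO, together with Flag (the control), Gadd45a or its mutant G39A, and each of these 3 groups has 2 arrays. RNA was extracted with TRIzol, checked for integrity, purified on RNeasy columns and amplified with a low-input labelling kit, per the labels' protocols. No label says that the replicates came from separate cultures, so p-values measure only the spread between these arrays.

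Per the file headers, the spot intensity values were made with Agilent Feature Extraction, and the submitters' processing notes give its version as 10.7. The processed intensity of each spot was background-subtracted and detrended within the array, per the file headers, with a surrogate value for dim spots, and had not been normalized between arrays. The deposited 0 or 1 marks of each spot say whether it was well above background, saturated or an outlier. No spot was saturated on any array. The deposited value table is on a log2 scale, and its columns follow the scanner intensity of their own array (lowest r 0.9989 over probes; highest r with another array 0.991). Its columns have medians of 6.17 each and sorted values that differ by at most 0.0673, so they were quantile normalized and not centred by gene, and their direction is that of the signal. The other steps behind this table are not given in the sources used here. Coordinates are those of the probes in the file headers' mouse build mm9.

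From the scanner files, the spots of each probe were averaged after control spots and spots marked as outliers had been left out, and each array's 75th percentile of log2 processed signal was subtracted. Of 41174 probes, 27668 were named through an accession in a RefSeq gene table (assembly GRCm38.p6, used for names only), and the others kept the name in the files. A probe entered the tests when it was well above background on both arrays of at least 1 group and kept an unmarked spot on every array, which left 24147 probes. Each gene name was represented by its probe of highest mean signal over the 6 arrays, which gave 15649 genes, of which 2694 carry only a clone, transcript or locus identifier. Where other probes of a named gene differ from it in sign, this is stated beside the gene. Where a probe was not well above background on either array of a group, its level there is only a bound. The ratio is then given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. No ratio is given where it is under 1. A p-value for a probe dim on both arrays of a group rests partly on dim signals, which can be surrogate values. It then does not measure only the spread between arrays.

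Groups were compared with limma 3.58 in R 4.3 (lmFit and eBayes on all 6 arrays, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. This model had 3 residual degrees of freedom. Gene lists were compared with the rest of the genes by limma's camera, testing both directions, with a preset correlation between genes of 0.01 and adjustment over the 25 lists with at least 5 tested members, of 26 lists fixed. The remaining list had too few measured members. The lists cover cell programmes, stress responses and markers of other cell types, and 517 of their 641 symbols were tested. Alternatives for lists were a correlation estimated from the data and limma's fry. The groups, tests, lists, naming rule and the alternatives other than those named below as added were chosen before the data were examined. The number of arrays limits the precision: the median standard error of a difference between groups was 0.318 (log2), and 0.117 with the replicate number as a block. The SE given beside single genes is that of the model without a block unless stated. It therefore also holds the difference between the replicate numbers.

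Genes are named by a fixed rule. It takes 12 genes of the question in every comparison. It then takes the 8 largest changes each way among genes past the threshold whose groups do not overlap, or, where fewer than 4 passed, the genes of smallest p up to 4 each way. It also takes up to 4 members of smallest p of each list past the threshold. Names that are only identifiers were left out. The same rule applied to the model with the replicate block was added after seeing the data.

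Arrays with the same replicate number deviated together. Their deviations from the group means correlated at 0.911 to 0.915 for each of the 3 pairs of groups. Signals correlated at 0.988 to 0.993 between arrays of the same number and at 0.919 to 0.921 between the arrays of the same group. The first principal component held 86.1% of the variance and parted the numbers. The numbers were therefore taken to pair the arrays, on the evidence of the data and not of the labels. Values with the replicate block stand beside the counts of genes and lists in each comparison. The 3 slides hold Flag and Gadd45a of replicate 1 (slide 3), G39A of replicate 1 alone (slide 1) and all groups of replicate 2 (slide 2), so slide was tried as a fixed and as a random block.

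Further alternatives were quantile or median scaling, normexp background correction (offset 50), the deposited value table, other filters on dim probes, marked spots kept, every probe or the mean of a gene's probes, only the groups compared, an intensity trend in the prior, and each array left out in turn. Combinations of the replicate block with another choice, and the comparison of replicate 2 with replicate 1 arrays, were added after seeing the data.

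The procedure was tested on simulated data for Gadd45a against Flag over 15649 genes, with 100 genes changed 2-fold and 100 changed 4-fold in each of 10 runs. With the replicate difference of these arrays left in, the model without a block recovered 0% of the 2-fold and 0% of the 4-fold changes, and the model with the replicate block recovered 78% and 98%, with 182 false calls over the runs. With no replicate difference, the model without a block recovered 83.3% and 98.1%. A list of 28 shifted genes was called in 10 of 10 runs and an unshifted one in 0 of 10, with the preset correlation. The simulated genes varied independently of each other. These runs therefore do not measure false list calls where genes move together, as in the interferon list, whose estimated correlation was 0.523.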

Results

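The series asks which genes Gadd45a regulates while fibroblasts are reprogrammed towards pluripotency. Gadd45a is a stress-inducible gene of growth arrest and DNA damage that has been linked to DNA demethylation. Mouse embryonic fibroblasts infected with SKO were profiled at day 8 in 3 groups of 2 arrays: SKO with the control Flag, SKO with Gadd45a, and SKO with G39A, which the labels describe as a negative mutant of Gadd45a. The labels do not spell out SKO; in this field the letters usually stand for Sox2, Klf4 and Oct4, the protein of Pou5f1. The share of spots well above background was 62.1% and 62.9% on the Flag arrays, 57.0% and 59.8% on the Gadd45a arrays, and 62.9% and 59.6% on the G39A arrays, in the order of replicates 1 and 2.

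Pou5f1, the core pluripotency factor, parted the replicate numbers in every group. Its probe (chromosome 17, 35647280 to 35647340, mm9) starts at base 910 of the transcript. From general knowledge of the gene, and not from a table used here, this lies in the coding part, which an introduced mouse copy would also carry. On the arrays labelled SKO replicate 1 its signal was 3851 in Flag, 5153 in Gadd45a and 6363 in G39A. On the arrays labelled SKO replicate 2 it lay between 3.6 and 4.4 and was not well above background, a difference of at least 228-fold. Klf4, a Krüppel-like factor, was bright on all 6 arrays, from 15458 to 19703 (probe on chromosome 4, 55540833 to 55540892). Sox2, a neural and pluripotency factor, was well above background only on the Flag replicate 2 array, at 21.9 (chromosome 3, 34550773 to 34550832). The Gadd45a probe (chromosome 6, 66985376 to 66985435) gave 1017 in Flag, 560 in Gadd45a and 1395 in G39A on the replicate 1 arrays, and 2309, 1870 and 2147 on the replicate 2 arrays. It was thus not brighter in the group labelled Gadd45a. The Klf4, Sox2 and Gadd45a probes start at bases 2160, 1846 and 878 of their transcripts. The limits of the coding sequences were not in the tables used here, so whether these probes read the introduced copies is open, and they check no label. If the O of SKO is a mouse Pou5f1 with this sequence, the replicate 2 signal goes against the label, so each direction below that rests on replicate 2 is that of the arrays labelled SKO.

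**Figure D1:**
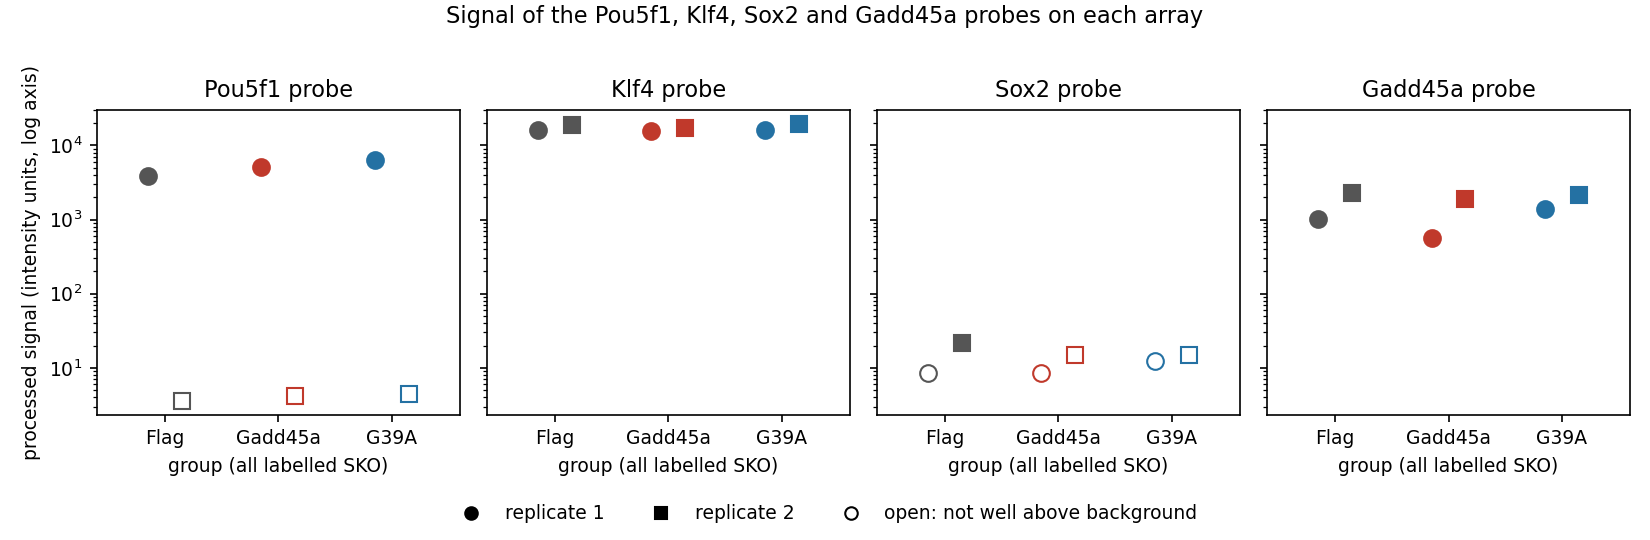
Processed signal (intensity units, log axis) of the Pou5f1, Klf4, Sox2 and Gadd45a probes on each of the 6 arrays, by group, with circles for replicate 1, squares for replicate 2 and open marks for spots not well above background. Pou5f1 lies between 3851 and 6363 on the replicate 1 arrays and between 3.6 and 4.4 on the replicate 2 arrays.

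In the cultures labelled Gadd45a, genes of the interferon response, the antiviral programme that cells switch on after sensing viral nucleic acids, rose against Flag. The median of the 28 measured members was 1.21 (log2; camera of limma, adjusted p = 4.27e-24), but adjusted p = 0.923 with an estimated correlation. The rise was uneven between replicates: the list median was 0.10 in replicate 1, with 21 members higher, and 2.34 in replicate 2, with all 28 higher and 24 of them at least 2-fold. Oasl1, a 2'-5'-oligoadenylate synthetase-like protein, differed by 0.57 in replicate 1 and 3.29 in replicate 2. Rsad2, which encodes the antiviral enzyme viperin, differed by 0.13 and 3.63, Ifih1, a sensor of double-stranded RNA, by 0.19 and 1.89, and Gbp2, an interferon-induced GTPase, by 0.36 and 1.26. Measured against the mean of the replicate 1 arrays, the median of the list was -1.01 on the Flag replicate 2 array and 0.74 on the Gadd45a replicate 2 array. The replicate 2 difference thus reflects a low Flag array as well as a higher Gadd45a array. No member passed limma's test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (1 with the replicate block, of which 0 passed).

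Genes of senescence and its inflammatory secretion, a programme of stressed fibroblasts, also rose as a list (24 members, median 0.11, camera adjusted p = 0.000626; adjusted p = 0.923 with an estimated correlation). The list median was -0.01 in replicate 1, with 11 members higher, and 0.27 in replicate 2, with 18 higher, and 8 were higher in both. The members of smallest p, none past the threshold, were among these 8: Plaur, the urokinase receptor, by 0.65 ± 0.25 (SE, n = 2 per group), the monocyte attractants Ccl7 and Ccl2 by 0.61 ± 0.25 and 0.70 ± 0.32, and the cytokine Il6 by 0.91 ± 0.44. With the replicate block their SE were 0.11, 0.20, 0.21 and 0.23, in this order. Genes of sterol synthesis fell as a list (23 members, median -0.14, adjusted p = 0.00262; adjusted p = 0.923 with an estimated correlation), with 17 members lower in both replicates. Among them were Dhcr7 (-0.48 ± 0.18) and Tm7sf2 (-0.56 ± 0.55), late reductases of cholesterol synthesis, Mvd (-0.31 ± 0.17) of the mevalonate pathway, and Nsdhl (-0.27 ± 0.17), of sterol demethylation. With the replicate block the SE of these sterol genes were 0.12, 0.10, 0.10 and 0.10, in this order. No member of either list passed limma's test over all genes or adjusted over the list alone; 0 senescence and secretion genes and 1 sterol gene had an unadjusted p under 0.05 (5 and 4 with the replicate block). The call of the senescence and secretion list ended without a filter on dim probes (camera adjusted p = 0.409). It also ended without Flag replicate 1 and without Gadd45a replicate 2, as did that of sterol synthesis. Leaving out 1 array brings the difference between the replicate numbers into the comparison. Those losses therefore do not separate a weak list from the replicate difference.

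With the replicate number as a block, 7 lists passed for Gadd45a against Flag in place of 3, and none of them did with an estimated correlation (adjusted p = 0.682 for each). The interferon (adjusted p = 1.04e-10), senescence and secretion (0.00947) and sterol (0.00474) lists were among them. In that model genes of glycolysis and hypoxia rose (26 members, adjusted p = 0.000752), with median differences of -0.04 in replicate 1 and 0.27 in replicate 2; the glucose transporter Slc2a1 differed by 0.45 and 0.44 in the replicates. Targets of p53 rose slightly (28 members, median 0.06, camera adjusted p = 0.0129), with 13 higher in both replicates and 6 lower in both. Among them were the stress cytokine Gdf15 (0.49) and Mdm2, the ubiquitin ligase of p53 (0.39), against Sesn1 (-0.41). Genes of G2 and mitosis fell (28 members, adjusted p = 0.00947), with 16 lower in both replicates and 0 higher in both; the proliferation marker Mki67 differed by -0.38. Markers of cartilage and bone fell (12 members, adjusted p = 0.00947), with medians of -0.18 and -0.34 in the replicates; the cartilage regulator Sox9 differed by -0.46 and the cartilage collagen gene Col2a1 by -0.39. Gdf15, Mdm2, Sesn1, Mki67, Slc2a1, Sox9 and Col2a1 were chosen as examples after their values were seen. None of these members passed the test over all genes, where the replicate block gave 0 calls.

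The other 22 lists did not pass for Gadd45a against Flag in the model without a block (adjusted p from 0.0941 to 0.859). The pluripotency network had a median of 0.05 over 15 members (adjusted p = 0.531), epithelial genes 0.29 over 14 (0.428), fibroblast genes -0.03 over 34 (0.859), and the DNA methylation and demethylation genes -0.03 over 29 (0.771). The pluripotency list had 35 genes and the epithelial list 33, so fewer than were listed were tested. The filter left out genes bright in replicate 1 alone, such as Pou5f1 and Cdh1, so these lists say nothing about such genes. Macrophage markers had medians of 0.24 and -0.26 in the replicates. Among the Hox genes, which set position along the body axis, 1 passed limma's test adjusted over the list alone, and 0 over all genes. It was the distal limb factor Hoxa13, which entered the tests only through its bright Flag arrays. Hoxa13 was not well above background on either Gadd45a array, so its p-value rests partly on dim signals. Test, mean and median differed in sign for the fibroblast, chromatin, oxidative phosphorylation, Hox, macrophage and neural lists.

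No single gene passed the threshold for Gadd45a against Flag (limma, 0 of 15649; lowest adjusted p = 0.712). At an unadjusted p under 0.05 there were 97 genes, 25 higher and 72 lower, where 782 would come by chance. The replicate difference lies in the residual of this model, which recovered 0% of the simulated 2-fold and 4-fold changes. A count of 0 or 97 from it therefore says little about Gadd45a. With the replicate block in limma 0 passed (lowest adjusted p = 0.127). There 1345 genes had an unadjusted p under 0.05, against the same 782 by chance. Genes are not independent, so this excess is no test. The named genes of smallest p did not pass the threshold. On the higher side they were led by St8sia6, a sialyltransferase (at least 7.06-fold higher in Gadd45a, probe on chromosome 2, 13578761 to 13578820). Next came Fam183b (at least 2.42-fold) and Ccr9, a chemokine receptor of gut-homing lymphocytes (at least 4.65-fold). Then came Prl, the hormone prolactin (log2 difference 0.94 in replicate 1 and 1.07 in replicate 2, SE 0.17). On the lower side stood Hoxa13 (at least 1.75-fold lower, chromosome 6, 52208856 to 52208915) and the galanin receptor Galr1 (at least 1.43-fold). With them were the lymphocyte GTPase Gimap5 (at least 2.11-fold) and the meiotic gene Hormad1, which was not well above background in Gadd45a. On the Gadd45a replicate 1 array their log2 signals were nearly the same, at -6.74, -6.81, -6.83 and -6.85. Their p-values thus rest partly on dim signals. The same rule on the replicate block also named Slc17a6, a vesicular glutamate transporter (1.62, adjusted p = 0.287), the B cell adaptor Blnk (0.83, 0.314), the protease Capn9 (at least 1.55-fold lower, 0.127), the synaptic scaffold Dlgap1 (at least 3.57-fold lower, 0.127), the ETS factor Erg (-1.92, 0.156; dim on 1 Gadd45a array) and the forkhead factor Foxi1 (at least 1.94-fold lower, 0.156). Gadd45a itself differed by -0.56 ± 0.84 (SE 0.27 with the replicate block). Klf4, Gadd45b, Gadd45g, Myc, Thy1, Trp53 and Cdkn1a differed by -0.24 to 0.30. None of these genes passed the threshold, and another Thy1 probe had the opposite sign. Pou5f1, Sox2, Nanog and the epithelial cadherin Cdh1 were not tested, because none was well above background on both arrays of any group. Like Pou5f1, Cdh1 was well above background on all 3 arrays of replicate 1 and on 0 of replicate 2, and Nanog on 2 and 0.

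With slide as a random block (consensus correlation 0.903), 19 genes passed for Gadd45a against Flag, 5 higher and 14 lower, all by 2-fold or more and the same way in both replicates (adjusted p from 0.0177 to 0.0442). Those with a gene name outside the identifiers were St8sia6, Fam183b, Prl and Slc17a6 among the higher and Capn9, Ccdc146, Cdca7l, Dlgap1, Foxi1, Hormad1, L3mbtl4 and Susd4 among the lower; Ccdc146, Cdca7l, L3mbtl4 and Susd4 were named after their values were seen. Cdca7l was not well above background in either group, and the other 13 lower genes were well above it on at most 1 Gadd45a array, so their 2-fold is that of the processed signal and not a measured ratio. Slide as a fixed block gave 0. Within the slides, which here are the replicate numbers, 82 genes differed at least 2-fold the same way in both (17 higher, 65 lower) and 16 in opposite ways. Among genes well above background on all 6 arrays the same counts were 5 higher, 4 lower and 3 opposite. The correlation of the replicate 1 and replicate 2 differences was 0.279 across genes, which are not independent replicates.

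**Figure D2:**
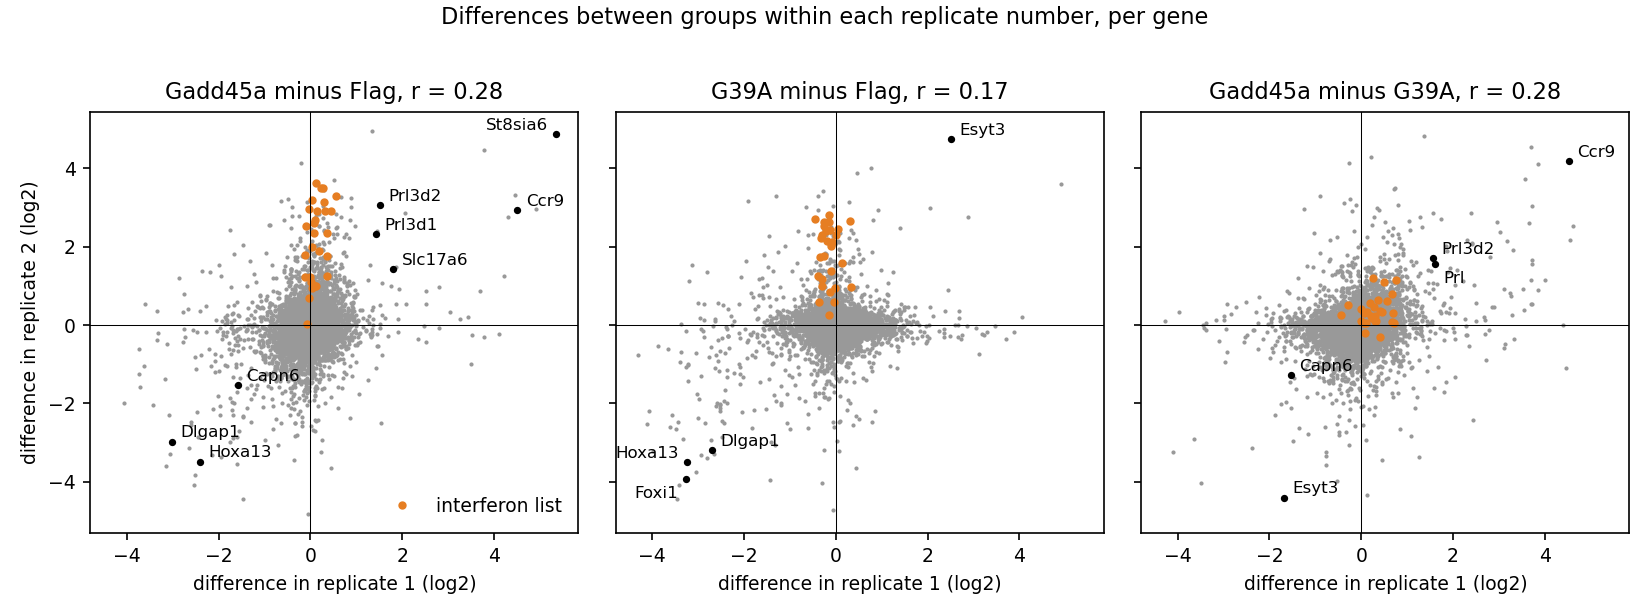
Log2 difference between groups within replicate 1 (x axis) and within replicate 2 (y axis) for each of 15649 genes, with interferon list members in orange and labelled genes in black. For both differences from Flag the interferon genes spread along the y axis only, with medians of 0.10 and 2.34 for Gadd45a and -0.15 and 2.06 for G39A.

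The mutant G39A is the design's control for Gadd45a. In cultures labelled G39A the interferon list was higher than on the same Flag arrays (median 0.95, camera adjusted p = 2.66e-16, but adjusted p = 0.966 with an estimated correlation). Its median was -0.15 in replicate 1, with 5 members higher, and 2.06 in replicate 2, with all 28 higher and 21 at least 2-fold. Ifi44, an interferon-induced protein, differed by 0.32 in replicate 1 and 2.66 in replicate 2, Ifih1 by 0.13 and 1.58, and Irf7, a regulator of interferon genes, by -0.10 and 2.01. Against the mean of the replicate 1 arrays, the list median was 0.43 on the G39A replicate 2 array and -1.01 on the Flag replicate 2 array. The Gadd45a and G39A differences in replicate 2 share that Flag array, so the second adds no separate evidence. No member passed limma's test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, with or without the replicate block. The call ended without the Flag replicate 2 array, but the difference between the replicate numbers enters that comparison.

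With the replicate block, 2 lists passed for G39A against Flag in place of 1: the interferon list (adjusted p = 1.12e-09) and S phase genes, which rose (28 members, median 0.06, adjusted p = 0.0273) with 13 higher in both replicates and 0 lower in both. Neither passed with an estimated correlation and the block (adjusted p = 0.977). The other 24 lists did not pass without the block (adjusted p of at least 0.924). The senescence and secretion list had a median of -0.04 and sterol synthesis one of -0.07. Macrophage markers had medians of 0.12 and -0.24 in the replicates. Hoxa13 passed limma's test adjusted over its list alone and not over all genes. This rests on the same Flag arrays as in Gadd45a and adds no separate evidence. It was dim on both G39A arrays too. Test, mean and median differed in sign for 9 lists, all with medians within 0.10 of 0, among them the pluripotency, epithelial, fibroblast and p53 lists.

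No gene passed for G39A against Flag (limma, 0 of 15649; lowest adjusted p = 0.953), with 82 at an unadjusted p under 0.05, 18 higher and 64 lower. The replicate block gave 0 as well (limma, lowest adjusted p = 0.115), with 451 at an unadjusted p under 0.05, where 782 would come by chance. Without the block, the replicate difference again lies in the residual of the model. The genes of smallest p, none past the threshold, were Esyt3, an extended synaptotagmin (at least 2.52-fold higher in G39A), Tcl1b3 (at least 1.54-fold), Ccdc187 (1.14 ± 0.34) and the major histocompatibility gene H2-T24 (1.05 ± 0.36; dim on 1 Flag array). On the lower side they were Hoxa13 (at least 2.36-fold lower), Foxi1 (at least 2.62-fold), Galr1 (at least 1.92-fold) and Gimap5 (at least 2.85-fold). These genes, with Capn9 and Dlgap1 below, were well above background only on the Flag arrays and entered the tests through them. Their p-values thus rest partly on dim signals. All were also named as lower in Gadd45a, against the same Flag arrays, so their return adds no separate evidence. The replicate block added Ttll13 (at least 1.99-fold higher, adjusted p = 0.991), the peptide transporter Tap2 (0.43, 0.991), Capn9 (at least 2.09-fold lower, 0.115), Dlgap1 (at least 4.82-fold lower, 0.133) and the cornified envelope gene Sprr1b (at least 1.23-fold lower, 0.149). Gadd45a differed by 0.09 ± 0.84 (SE 0.27 with the replicate block). With slide as a random block 3 genes passed, all lower: Foxi1 (adjusted p = 0.0312) and the unnamed transcripts AK043453 and AK050511, the latter pair chosen after their values were seen. Within the replicate numbers 74 genes differed at least 2-fold the same way in both (7 higher, 67 lower) and 18 in opposite ways, with a correlation of 0.166 across genes (rank correlation -0.0372). Among genes well above background on all 6 arrays the counts were 0 higher, 1 lower and 2 opposite. Only the replicate 2 difference lies within a slide, because G39A replicate 1 had a slide of its own.

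**Figure D3:**
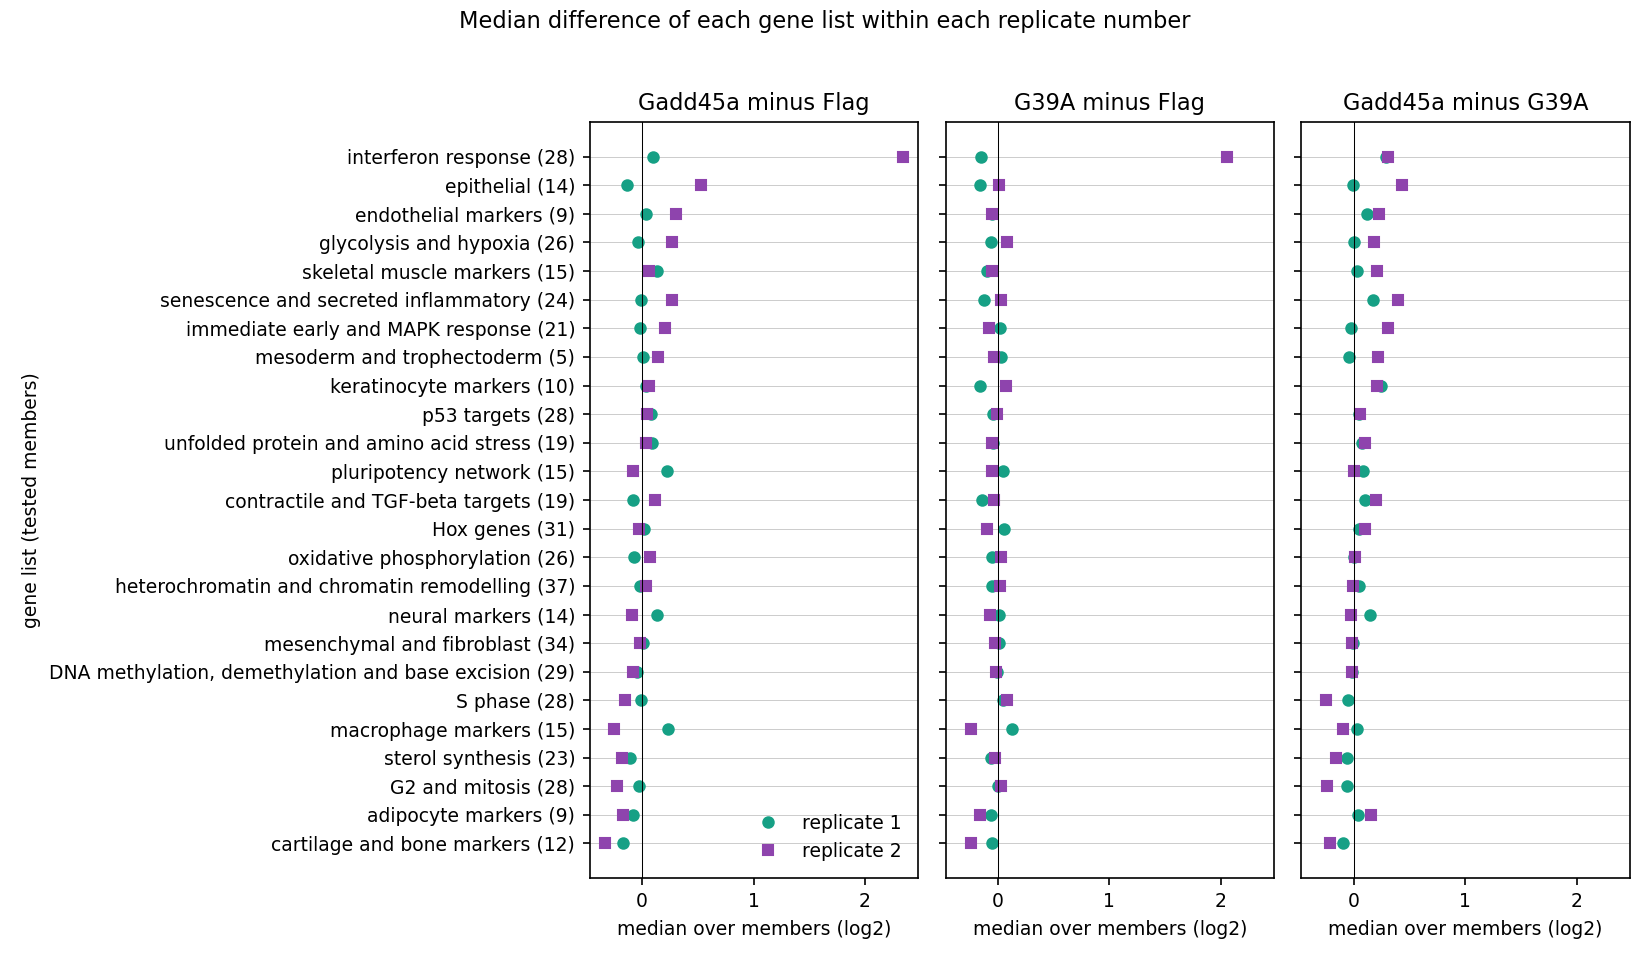
Median log2 difference over the tested members (number in brackets) of each of the 25 gene lists within replicate 1 (circles) and replicate 2 (squares), for the 3 comparisons. The interferon list reaches 2.34 and 2.06 in replicate 2 against Flag, with 0.10 and -0.15 in replicate 1.

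Gadd45a was compared with its mutant G39A directly. The replicate 1 arrays of these groups lay on different slides, so only the replicate 2 differences lie within a slide. The senescence and secretion list rose in Gadd45a (24 members, median 0.24, camera adjusted p = 0.00224; adjusted p = 0.856 with an estimated correlation), with 14 members higher in both replicates and 1 lower in both. The cytokine Il11 differed by 1.08 ± 0.42, Plaur by 0.64 ± 0.25, Ccl2 by 0.65 ± 0.32 and Ccl7 by 0.58 ± 0.25, none past the threshold. The interferon list rose (median 0.25, adjusted p = 0.0160; adjusted p = 0.856 with an estimated correlation), with medians of 0.29 in replicate 1 and 0.31 in replicate 2 and 23 members higher in both. The RNA sensor Ddx58 differed by 0.50 ± 0.34, Oasl1 by 0.96 ± 0.73, Usp18, which removes the ubiquitin-like protein ISG15, by 0.74 ± 0.91 and Gbp2 by 0.38 ± 0.39. With the replicate block the interferon call ended (adjusted p = 0.0751) and that of the senescence and secretion list stood (adjusted p = 0.00246; adjusted p = 0.601 with an estimated correlation). No member passed limma's test over all genes or adjusted over the list alone, and 0 of either list had an unadjusted p under 0.05. With the block 6 senescence and secretion genes did, and 2 members, Plaur and the cell-cycle inhibitor Cdkn2a, passed adjusted over the list alone; Cdkn2a was named after its values were seen. Both calls ended without a filter on dim probes (camera adjusted p = 0.131 for senescence and secretion and 0.656 for interferon). They also ended without G39A replicate 1 and without Gadd45a replicate 2. There the replicate difference enters the comparison, so these losses do not separate a weak list from that difference.

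With the replicate block, 8 lists passed for Gadd45a against G39A in place of 2, none of them with an estimated correlation (adjusted p = 0.601 for each). Genes of G2 and mitosis fell (adjusted p = 0.00130), with medians of -0.06 and -0.24, 16 members lower in both replicates and 0 higher in both, and genes of S phase fell (adjusted p = 0.00126), with 18 lower in both. The mitotic kinase gene Bub1 differed by -0.40 and Bub1b by -0.37. Sterol synthesis genes fell (adjusted p = 0.0174). Genes of glycolysis and hypoxia (adjusted p = 0.0135), of the unfolded protein response (0.0242), of the immediate early response (0.0306) and of contraction (0.0331) rose. In replicate 1 the medians were 0.00 for glycolysis and hypoxia and -0.02 for the immediate early genes, against 0.18 and 0.31 in replicate 2. The growth-factor gene Vegfa differed by 0.33, the immediate early genes Fosl1 and Egr1 by 0.46 and -0.61, and the contractile genes Cnn1 and Tpm2 by 0.34 and 0.27. Bub1, Bub1b, Vegfa, Fosl1, Egr1, Cnn1 and Tpm2 were chosen as examples after their values were seen, and none passed over all genes. The other 23 lists did not pass without the block (adjusted p from 0.0587 to 0.962), among them the pluripotency network (0.738) and the DNA methylation and demethylation genes (0.738), for both of which the signs of the mean and the median differed. The pluripotency list again lacks the genes bright in replicate 1 alone.

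No gene passed for Gadd45a against G39A (limma, 0 of 15649; lowest adjusted p = 0.520), with 114 at an unadjusted p under 0.05, 66 higher and 48 lower. The replicate block gave 0 (limma, lowest adjusted p = 0.0949), with 1389 at an unadjusted p under 0.05, where 782 would come by chance. Without the block, the residual holds the replicate difference here too. Of the genes of smallest p, none past the threshold, Prl differed by 1.58 ± 0.17 (with 1 G39A array not well above background). Ccr9 differed by at least 4.18-fold and the keratin-associated gene Krtap1-5 by at least 1.90-fold. The T cell receptor segment Trav9d-3 was higher too. Only 1 of its 2 Gadd45a arrays was well above background, so no bound on its ratio is given. Cdca7l, a partner of Myc, was lower by at least 1.14-fold, Esyt3 by at least 1.68-fold and the homeobox gene Prox2 by at least 1.28-fold, and Stxbp6, which binds syntaxin, differed by -1.11 ± 0.20. The replicate block added Fam183b (at least 2.18-fold higher, adjusted p = 0.229), Blnk (1.07, 0.229), Capn6, a microtubule-binding calpain (-1.40, 0.219; another probe had the opposite sign), Erg (-1.52, 0.235; dim on 1 array of each group) and Plxdc1, a plexin-domain protein of vessels (-1.14, 0.255), and Sprr1b, which was not well above background in either group. Gadd45a differed by -0.65 ± 0.84 (SE 0.27 with the replicate block). With slide as a random block 7 genes passed, 5 higher, with Prl, Gm2861 and AK043453 (not well above background in either group) among them, and 2 lower, Cdca7l (adjusted p = 0.0494) and the transcript AK081527; Gm2861, AK043453 and AK081527 were chosen after their values were seen. Within the replicate numbers 74 genes differed at least 2-fold the same way in both (50 higher, 24 lower) and 20 in opposite ways, with a correlation of 0.277 across genes; of those well above background on all 6 arrays, 7 were higher, 5 lower and 0 opposite.

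**Figure D4:**
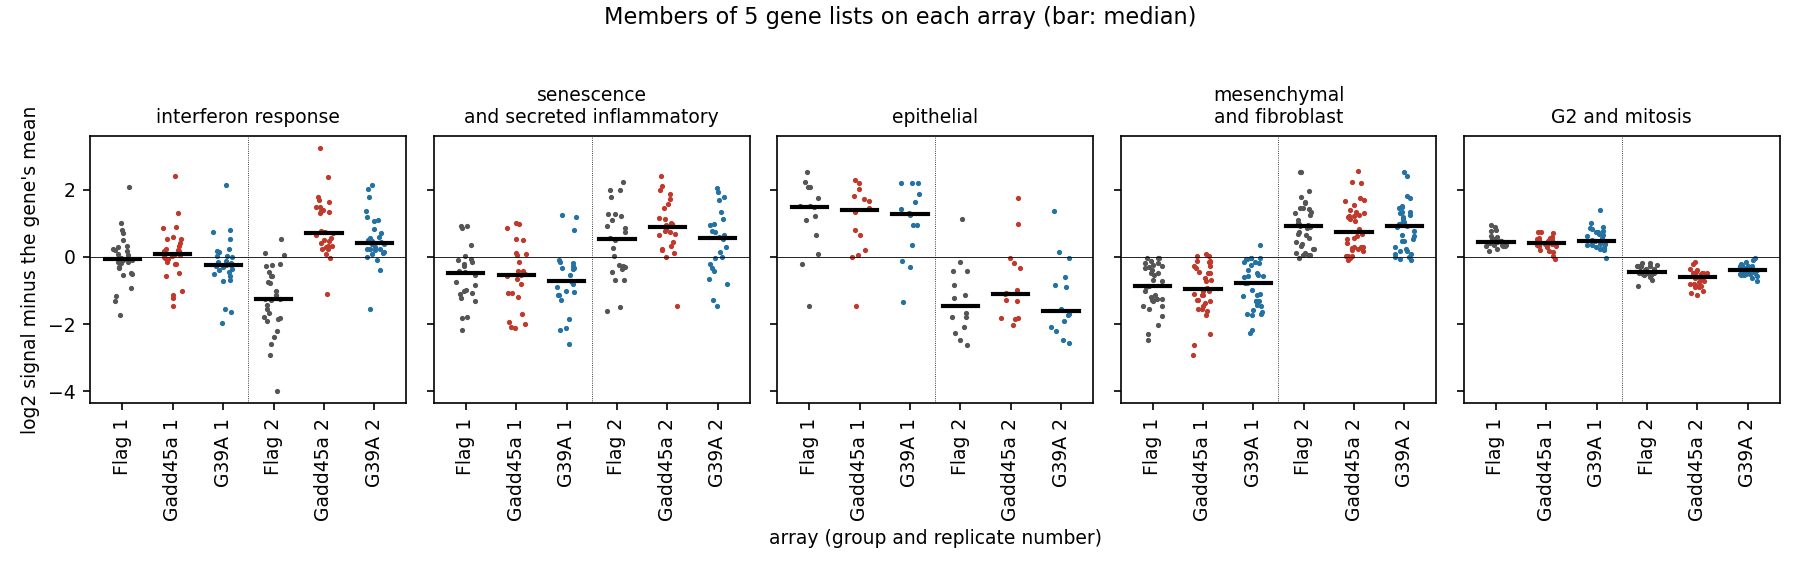
Log2 signal of each member of 5 gene lists minus that gene's mean over the 6 arrays (points), with the list median as a bar, on each array. Interferon genes have medians of -1.26 on the Flag replicate 2 array and 0.72 and 0.42 on the Gadd45a and G39A replicate 2 arrays, and the other lists part by replicate number.

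The differences of Gadd45a and of G39A from Flag were compared across genes, since the mutant is the control for Gadd45a. They correlated at 0.451 (Pearson; Spearman 0.313). Unchanged groups simulated 100 times against the same Flag arrays gave a mean of 0.497 and at most 0.537. The covariance was 0.0422 against a simulated 0.0297, so the shared part was estimated at 0.0126. Across replicate numbers, where no Flag array is shared, the correlation was 0.124 (Gadd45a in replicate 1 with G39A in replicate 2) and 0.0437 (the reverse). Within replicate numbers, where both differences share 1 Flag array and no simulated value was made, it was 0.407 in replicate 1 and 0.556 in replicate 2 (0.531 without the interferon genes). The shared controls alone gave a correlation at least as high as the pooled one, and leaving out 1 array moved it to between 0.166 and 0.885.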

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

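The number of genes past the threshold was 0 in every comparison and stayed 0 under most alternatives. Alternatives without a block keep the replicate difference in the residual. In the simulations the model without a block recovered 0% of the changes, so a count of 0 there says little. With slide as a random block it was 19 for Gadd45a against Flag, 3 for G39A against Flag and 7 for Gadd45a against G39A. The replicate block changed no gene count by itself. With quantile normalization, the replicate block gave 1 gene for Gadd45a against G39A, and with an intensity trend it gave 1 for Gadd45a against Flag, Capn6 (adjusted p = 0.0367). The gene lists past the threshold were 3, 1 and 2 (Gadd45a against Flag, G39A against Flag, Gadd45a against G39A). They were 7, 2 and 8 with the replicate block, 7, 6 and 12 with slide as a fixed block, 0, 0 and 0 with an estimated correlation between genes, and 0, 0 and 0 with fry. With normexp, offset 50, Gadd45a against G39A had 4. The replicate block gave 7, 2 and 7 lists with quantile normalization, 9, 2 and 6 with normexp, 7, 2 and 11 with the filter of all 6 arrays, and 0, 0 and 0 with an estimated correlation. Leaving out each array in turn gave 4 to 13, 1 to 9 and 2 to 11 lists, and a correlation of the differences of Gadd45a and G39A from Flag of 0.166 to 0.885. For Gadd45a against Flag the lists were 7 without Flag replicate 1, 10 without Gadd45a replicate 1, 13 without Flag replicate 2 and 8 without Gadd45a replicate 2. For G39A against Flag they were 8 without Flag replicate 1, 9 without G39A replicate 1, 6 without Flag replicate 2 and 4 without G39A replicate 2. For Gadd45a against G39A they were 11 without Gadd45a replicate 1, 6 without G39A replicate 1, 7 without Gadd45a replicate 2 and 8 without G39A replicate 2. The correlation was 0.885 and 0.874 without Flag replicate 1 and 2, 0.235 and 0.201 without Gadd45a replicate 1 and 2, and 0.166 and 0.227 without G39A replicate 1 and 2. A group left with 1 array differs from the others in its replicate numbers, so the replicate difference enters these comparisons. For the other moves, slide as a random block among them, the cause was not tested. Over the named genes, 11 calls were gained, all with slide as a random block, and 70 values without a call took the other sign. Over the lists past the threshold in some model, 27 medians took the other sign, 35 calls were lost and 92 gained. The interferon list had a median from 0.49 to 1.72 for Gadd45a against Flag, from 0.09 to 1.46 for G39A against Flag and from -0.16 to 0.67 for Gadd45a against G39A. The median of the senescence and secretion list for Gadd45a against Flag ran from -0.49 to 0.95, and that of G2 and mitosis from -0.66 to 0.42.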

Other observations

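The comparison of replicate 2 with replicate 1 arrays, and the choice of genes named from it, were made only after the data had been seen. Replicate numbers carry no biological label, yet they parted the arrays far more than the introduced gene did. Of 15649 genes, 9041 (57.8%) differed past the threshold in limma, 5366 higher and 3675 lower in replicate 2, and 3224 of them at least 2-fold. The p-values measure the spread among arrays of the same number, not the spread between repeats of a number. All replicate 2 arrays lay on slide 2 and no replicate 1 array did, so number and slide cannot be told apart. The replicate 2 arrays showed more of the fibroblast programme (list median 1.76, camera adjusted p = 2.26e-09, but adjusted p = 0.0717 with an estimated correlation). Of its 34 members, 29 were past the threshold as higher and 0 as lower. The collagen gene Col3a1 was higher by 3.01, the matrix genes Lum and Postn by 5.05 and 3.83, the receptor Pdgfra by 4.79 and the fibroblast surface marker Thy1 by 2.67. Contractile genes were higher too (median 1.62, adjusted p = 3.29e-04; 0.416 as adjusted p with an estimated correlation), with smooth muscle actin Acta2 at 2.69. The replicate 1 arrays showed more epithelial expression (median -2.90, camera adjusted p = 1.34e-04, but adjusted p = 0.412 with an estimated correlation). Of the 14 members, 11 were past the threshold as lower in replicate 2 and 1 as higher. The simple-epithelium keratin Krt8 was at -3.75, the desmosomal plakin Dsp at -4.68 and the epithelial integrin Itgb4 at -5.94. Replicate 1 also had more mitotic gene expression (median -0.94, 27 of 28 past the threshold, adjusted p = 3.2e-10; 0.412 as adjusted p with an estimated correlation) and S phase expression (median -0.64, adjusted p = 9.93e-07; 0.417 as adjusted p with an estimated correlation). Also lower in replicate 2 were keratinocyte markers (median -1.20, adjusted p = 0.00133), neural markers (-1.36, 0.00469), sterol synthesis (-0.22, 0.00469) and immediate early genes (-0.14, 0.0179), and also higher were unfolded protein (0.68, 0.00286), glycolysis (0.86, 0.00469), senescence and secretion (1.20, 0.00658) and p53 target genes (0.45, 0.0327), with adjusted p of at least 0.272 for each with an estimated correlation. The interferon list was not past the threshold between the replicate numbers (adjusted p = 0.861). Genes bright in 1 replicate number only, such as Pou5f1 and Cdh1, had been left out by the filter, so the pluripotency list does not test whether that programme was present in replicate 1 alone.

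Genes bright on all 6 arrays that differed at least 2-fold the same way in both replicates are leads that did not pass the test over all genes with or without the replicate block, and they were picked after their values were seen. The placental prolactin genes Prl3d1 and Prl3d2 differed between Gadd45a and Flag: Prl3d1 by 1.44 and 2.32 in replicates 1 and 2, and Prl3d2 by 1.52 and 3.05. Against G39A the differences were 1.92 and 1.47 for Prl3d1 and 1.56 and 1.71 for Prl3d2. Slc17a6, called only with slide as a random block (adjusted p = 0.0442), was higher than in Flag by 1.81 and 1.42, and Sprr1a, a cornified envelope gene, by 1.25 and 1.14. The calpain Capn6 stood at -1.57 and -1.53 against Flag (called only with the replicate block and an intensity trend; another of its probes had the opposite sign against G39A), the p38 activator Map2k6 at -1.19 and -1.62, and the vessel protein Plxdc1 at -1.11 and -1.35. Prim2, a primase subunit, was higher by 1.57 and 1.07, and Crispld1 stood at -1.30 and -1.09, and neither recurred among the genes against G39A. The signs of the other 7 against G39A rest on the same Gadd45a arrays and add no separate evidence. In replicate 1 each difference from G39A is also a difference between slides. G39A against Flag had a single such gene, the synaptic adaptor Apba1 (-1.02 and -1.27). The filtered list of 9 genes for Gadd45a against Flag and 12 against G39A is short enough to check by PCR on new cultures.

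For the split of the replicate numbers, the tests of array splits and of other cells were chosen only after the result was seen. The 3 against 3 arrays give 10 splits, too few for a share under 0.05, so the count of splits could not decide against chance. Only 1, the real split, gave 9041 genes, and the highest other gave 0. Signals correlated at 0.988 to 0.993 within a number and at 0.919 to 0.921 between the arrays of the same group. These ranges lie apart, which argues against chance spread between single arrays as the source of the split. A fault of single probes would leave the other probes of a gene without the difference, but 97.8% of 1349 other probes had its sign, so this explanation fails. A larger share of cells other than fibroblasts in the replicate 1 cultures would put their marker lists lower in replicate 2. The medians ran from -2.90 to 1.89, but the highest, that of macrophage markers, was not past the threshold (adjusted p = 0.0725), so this and a change within the cells cannot be told apart. The cause of the split stays open, and the Pou5f1 probe, at least 228-fold apart, with Cdh1 and Nanog bright on 3 and 2 arrays of replicate 1 and 0 of replicate 2, makes the factors of each culture the first thing to check.

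For the interferon genes, higher in Gadd45a and G39A than in Flag mainly in replicate 2, the test of macrophages was chosen only after the result was seen. Normalization or background correction could make such a shift. But over 4 other ways to scale or correct the signals, the smallest list median against Flag in replicate 2 was 1.66. This was G39A with normexp, where replicate 1 gave -0.15. Macrophages in these cultures would raise their own markers, yet the upper quartile of the 15 macrophage markers was 0.195, with medians of -0.256 in Gadd45a and -0.245 in G39A. Against the mean of the replicate 1 arrays the list median was -1.01 on the Flag replicate 2 array and 0.74 and 0.43 on those of Gadd45a and G39A. Both differences in replicate 2 share that single Flag array, and the cause stays open.

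For the differences from Flag that repeat between replicates, mostly as genes lower than in Flag, the test of dim probes in G39A was chosen only after the result was seen. If dim probes made the repeat, genes bright on all 6 arrays would not share it. In Gadd45a their correlation between replicates was 0.223 and that of the other genes 0.314, with a bound of 0.2 set for it. Some correlation thus remained among bright genes. The bootstrap SE (0.0146) treats genes as independent, which they are not, so it cannot place 0.223 above the bound. Of the bright genes at 2-fold or more in both replicates, 5 were higher, 4 lower and 3 opposite, so the lean to lower genes was not seen among them. In G39A the bright genes gave -0.0532 (bootstrap SE 0.0101, with the same limit) and the others 0.287. A gene lost to background leaves the bright genes by its own fall, so dim probes and a real loss cannot be told apart in G39A. Fewer spots above background on the Gadd45a arrays would put the repeating genes among dim probes and on the lower side. Of the 82 repeating genes, 9 were bright on all 6 arrays (5 higher, 4 lower), 89.0% were dim on some array and 83.6% of those were lower, so this and a real loss of weakly expressed transcripts cannot be told apart.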
